A study of Drosophila melanogaster with 4 samples.

How the data were processed

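Wing imaginal discs, the larval epithelia that form the adult wing and thorax, were taken from Drosophila melanogaster larvae of the third instar reared at 25 °C, per the labels' protocols. The series holds 4 samples with 1 library each: a chromatin immunoprecipitation (ChIP) library for H4K20me1 in wild type, its input library, an RNA library from wild type and an RNA library from Polycomb RNAi. Wild type here is the Act5C-GAL4 driver line, in which the yeast activator GAL4 is expressed from an actin promoter. In the RNAi discs the same driver switches on a transgene for a double-stranded RNA against Polycomb. The RNA libraries were made from total RNA without strand information, per the labels' protocols, so overlapping and antisense genes cannot be told apart. The wild-type genotype on the labels carries the CyO balancer chromosome and that of the RNAi discs names none. Near-identical gene copies, such as the Hsp70 and Mst84D genes, can share reads, and how these were divided is not given in the sources used here.

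The authors deposited FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for named genes, 1 column per RNA library, with no counts. The submitters' processing notes name CASAVA 1.4, Bowtie 1.0.0, TopHat2 2.0.11, Cufflinks and SICER and the genome build dm3, without saying which tool made which file. The gene annotation, the settings and any filter are not given in the sources used here. The authors also deposited H4K20me1 peak intervals with a score per peak, from the single ChIP sample. The scale of that score is not given in the sources used here. It is used below only to rank peaks within that list. No file of the input library was used here.

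The FPKM table held 15627 named genes. A further row named only by a dash, with 0.127% of the summed FPKM in wild type and 0.206% in Polycomb RNAi, was left out. Because FPKM is scaled to the mapped fragments, a few very abundant transcripts can shift every other value. The largest entry, CG41421, took 9.41% of the summed FPKM in wild type and 16.4% in Polycomb RNAi. The files give no sequencing depth. Values below 0.3 FPKM still carried traces of whole reads. Among 1159 genes between 0.005 and 0.3 FPKM in both libraries, the most frequent ratio of the values was 0.95, with 19.4% of genes within 5% of it. The mean at 6 other ratios was 2.78%, but a ratio picked as the most frequent holds more genes by its choice. Relative to 0.95, ratios of 2 to 1 and of 1 to 2 held 9.23% and 6.47% of genes. A ratio of 0.95 is expected if a read was worth 0.95 times as much in the RNAi library. The depth of that library would then be about 1.05 times that of wild type. The absolute depth stayed unknown, and no counting interval is given for an expression value.

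The difference per gene was log2((Polycomb RNAi FPKM + 1)/(wild-type FPKM + 1)). The pseudocount of 1 understates the change of genes with low values. Genes with an FPKM of at least 1 in either library were tested, and those at least 2-fold apart on this scale were counted as higher or lower. Within 2-fold means on this scale, so low genes within it can be more than 2-fold apart in FPKM. A gene low in wild type can enter a list through the RNAi library alone, so the median of a list with such genes depends on this minimum. With 1 library per genotype there is no replicate error. No p-value is given, and "higher" and "lower" compare these 2 libraries only. For 32 gene lists with at least 5 tested members, the median difference was placed among the medians of 10000 random lists of the same size, drawn with replacement from 20 bins of mean expression. A percentile from this describes the libraries and is no test across samples, since genes are not replicates. If genes varied independently, chance alone would put about 1.6 of the 32 lists outside the central 95%. Members of a list that vary together would put more outside, so this number is no yardstick for the lists here.

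Before the data were examined, the 35 gene lists, the 2-fold rule, the other settings to be tried and the rule for named genes were fixed. The rule names Pc, the 8 Hox genes, the 10 largest differences in each direction among genes reaching 5 FPKM, and up to 4 members per list with the largest differences. Of the list members, 16 were not found in the table under the symbols tried. Genes or list members named outside this rule were chosen after their values were seen. These included the patterning genes vg, kn, rho, wg, dpp, sd, hth and tup, the Polycomb targets en, inv, disco, bab2, mid, lbl, al, ap and Doc3, and N, Dl, Drs, Mtk, twi, Mef2, Fbp1, dj, vas, bam, upd2, upd3 and emc, the ranking of protein-coding genes, and the genes named for neighbouring or shared names, such as Nplp4, CG15353, fd96Ca, cv-2, wash, CG13176 and m4. Table names were matched to a gene table of the Release 6 assembly for symbols, gene class and gene order only. Of the 15627 names, 14965 (95.8%) matched a single gene. No coordinate of that assembly is given, because the peaks are on dm3.

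An overlap of peaks with genes was intended but not made, since gene positions of the dm3 build were not used here. Peak number, width, score and chromosome were described instead. Peak starts lay on multiples of 200 bp and ends 1 bp short of them, so intervals were read as closed and counted from 0, and are given counted from 1. Shares of peaks carry exact (Clopper-Pearson) 95% intervals, which cover counting error only. Alternatives were a pseudocount of 0.1 or 5, median centring, scaling each column to a sum of 1000000, no expression minimum or one of 5 FPKM, thresholds of 1.5-fold and 4-fold, and matching in 50 bins. The procedures were tested on simulated data for this comparison with 8387 genes. There the 2-fold rule recovered 100% of genes simulated with a log2 change of 1.5 and 100% of those with 2.5. The genes simulated as changed all had at least 5 FPKM in wild type, so recovery of genes with lower expression was not tested. Of random lists of unchanged genes, 4.0% fell outside the central 95%. That simulation assumed small noise between libraries, independent between genes, which these data cannot measure. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.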

Results

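RNA was profiled in wing discs of wild-type and Polycomb RNAi larvae, with 1 library per genotype, and H4K20me1 was mapped by ChIP sequencing in wild-type discs. Polycomb (Pc) is a chromodomain protein of the repressive complex PRC1. H4K20me1 is the monomethyl mark placed on a lysine of histone H4 by the enzyme PR-Set7. The series title sets the question whether Polycomb also has a positive role in transcription through this mark. The expression table listed 15627 genes, of which 8335 reached 1 FPKM in wild type and 8500 in Polycomb RNAi. Genes listed at exactly 0 numbered 4170 in wild type and 3292 in Polycomb RNAi. No replicate libraries exist for any group, so all differences below are between single libraries and have no replicate error and no p-value.

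The targeted gene was checked first. Pc RNA stood at 14.6 FPKM in wild type and 13.0 FPKM in Polycomb RNAi, a log2 difference of -0.16. This lies just below the lower quartile of all tested genes, whose quartiles were -0.14 and 0.14. The file gives no values along the gene, so reads of Pc and of the RNAi transgene are not separated, and the Pc value does not check the labels.

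The Hox genes, which set segment identity and are classical targets of Polycomb repression, were much higher in the Polycomb RNAi library. Of the 8 Hox genes, 5 were tested and 4 of these were at least 2-fold higher. Abd-B, which specifies posterior abdominal segments, was 0.194 FPKM in wild type and 36.7 FPKM in Polycomb RNAi. Ubx, which specifies the haltere instead of the wing, was 2.23 and 60.8 FPKM. Scr was 0.408 and 24.5 FPKM, and abd-A was 1.03 and 3.16 FPKM. Antp, the Hox gene normally active in the wing disc, was 18.8 FPKM in wild type and 14.2 FPKM in Polycomb RNAi. The head Hox genes stayed below 1 FPKM in both libraries, with lab at 0.128 and 0.181 FPKM, Dfd at 0 and 0.358 FPKM and pb at 0 and 0.159 FPKM. The median log2 difference of the 5 tested Hox genes was 4.18, above that of all 10000 matched random lists, whose central 95% ran from -0.42 to 0.42. Scr and Abd-B passed the expression minimum through the Polycomb RNAi library only, and the median was 0.74 over all 8 Hox genes without a minimum and 2.45 with a pseudocount of 5, each again above all random lists. The log2 difference of abd-A was 1.04, and 0.99, below the 2-fold threshold, with both libraries scaled to the same sum.

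Across all 8800 tested genes, 388 (4.41%) were at least 2-fold higher in Polycomb RNAi, 282 (3.20%) were at least 2-fold lower, and 8130 (92.4%) lay within 2-fold. The median log2 difference was -0.0032, and the correlation between the libraries across genes was 0.945 on the log2 scale. Among genes reaching 5 FPKM the numbers were nearly equal, at 189 higher and 186 lower. Of the 388 higher genes, 119 were listed at 0 in wild type, and of the 282 lower genes, 48 were listed at 0 in Polycomb RNAi. Without the small RNA names the numbers were 343 higher and 245 lower. For protein-coding genes alone, with names of the same gene summed, they were 307 higher and 205 lower of 8208.

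**Figure D1:**
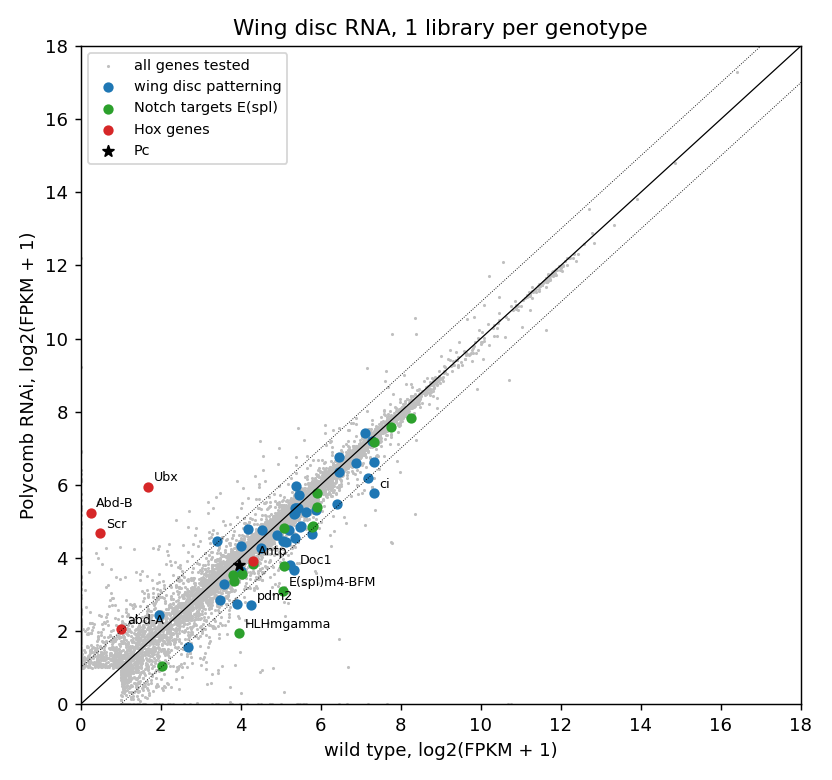
Expression in Polycomb RNAi (y axis) against wild type (x axis), both as log2(FPKM + 1), for the 8800 tested genes in grey, with the lists of Hox, wing patterning and Notch target genes coloured and Pc as a star. The solid line marks equal values and the dotted lines a 2-fold difference; Abd-B, Ubx and Scr stand far above the lines, while ci and Doc1 lie below them.

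Transcription factor genes known as Polycomb targets differed in both directions. Of the 76 in the list, 47 were tested, 10 were at least 2-fold higher in Polycomb RNAi and 6 at least 2-fold lower. Random matched lists gave on average 2.89 higher and 2.00 lower. Besides the 3 Hox genes of the list, the higher genes were cad, a hindgut and posterior determinant (0.0851 and 3.04 FPKM in wild type and Polycomb RNAi), disco (2.01 and 6.50 FPKM), bab2 (11.2 and 28.7 FPKM), tup (9.58 and 21.0 FPKM), mid (2.97 and 7.69 FPKM), lbl (0.24 and 1.94 FPKM) and oc (0.0985 and 1.37 FPKM). The lower genes were the T-box genes Doc1 (39.6 and 11.8 FPKM), Doc2 (16.4 and 3.98 FPKM) and Doc3 (22.1 and 9.52 FPKM), and the homeobox genes al (38.4 and 12.3 FPKM), Dll (36.7 and 13.1 FPKM) and ap (143.9 and 71.3 FPKM). Of the lower genes, ap lay just past the 2-fold threshold. The adjacent target genes en (42.1 and 40.6 FPKM) and inv (40.5 and 40.4 FPKM) had nearly equal values. The list's median was 0.31, above that of all 10000 random lists, and 0.31 again without its Hox genes. It was 0.15 without an expression minimum and 0.19 with a minimum of 5 FPKM, each again above all random lists. Marker lists of other cell types differed too, with medians of 0.27 for haemocyte and 0.23 for muscle markers. Those of tracheal, fat body, and gut and salivary gland markers were -0.24, -0.34 and 0.87, the last being 0.41 without an expression minimum.

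Wing patterning genes were lower in the Polycomb RNAi library as a group. All 40 in the list were tested, 8 were at least 2-fold lower and 1, tup, was at least 2-fold higher. The median was -0.33, below that of all 10000 random lists, whose central 95% ran from -0.07 to 0.05. The transcription factor gene ci, the effector of Hedgehog signalling, was 159.3 FPKM in wild type and 53.3 FPKM in Polycomb RNAi. The POU gene pdm2 was 18.2 and 5.54 FPKM. Outside the fixed rule, the wing selector vg was 54.2 and 24.0 FPKM, the vein gene kn 14.1 and 5.64 FPKM, and rho, which activates EGF receptor ligands in veins, 5.38 and 1.96 FPKM. The other lower genes were Doc1, Dll and ap, the last just past the 2-fold threshold. Other members of the network were closer between the libraries, such as wg (43.0 and 51.3 FPKM), dpp (21.5 and 18.3 FPKM), sd (116.7 and 95.2 FPKM) and hth (137.8 and 169.1 FPKM). This list shares 10 genes with the list of Polycomb targets. In the same libraries the lists of haemocyte and muscle markers had medians of 0.27 and 0.23, and those of tracheal and fat body markers -0.24 and -0.34. That of gut and salivary gland markers was 0.87, or 0.41 without an expression minimum.

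The list of Notch targets had a median below the random range, with a minority of its genes at least 2-fold lower. Of 16 tested genes in the list of Notch targets, which holds E(spl) and Bearded family genes besides dpn and Him, 4 were at least 2-fold lower and none at least 2-fold higher. HLHmgamma was 14.6 FPKM in wild type and 2.84 FPKM in Polycomb RNAi, E(spl)m4-BFM 32.4 and 7.52 FPKM, E(spl)m8-HLH 33.0 and 12.7 FPKM, and HLHm5 3.12 and 1.06 FPKM, which lay just past the 2-fold threshold and just inside it with median centring. Their median of -0.46 lay below that of all 10000 random lists. In the same libraries the medians were 0.27 for haemocyte, 0.23 for muscle, -0.24 for tracheal and -0.34 for fat body markers. For gut and salivary gland markers the median was 0.87, or 0.41 without an expression minimum. Notch itself was 87.0 and 81.3 FPKM, and its ligand gene Dl 49.0 and 37.4 FPKM. Of 11 tested proneural and sensory organ genes, only sens was at least 2-fold lower with the pseudocount of 1 (3.70 and 1.06 FPKM). The genes phyl (1.76 and 0.667 FPKM) and cato (1.76 and 0.711 FPKM) were more than 2-fold apart in FPKM and passed with a pseudocount of 0.1, while emc was 305.8 and 428.6 FPKM. The proneural gene ac was 33.6 and 16.6 FPKM, a ratio of 2.02 and a log2 difference of -0.97 with the pseudocount of 1, and the list's median was -0.39, at percentile 0.07. That median moved to -0.08, inside the random range, when only genes reaching 5 FPKM were kept.

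**Figure D2:**
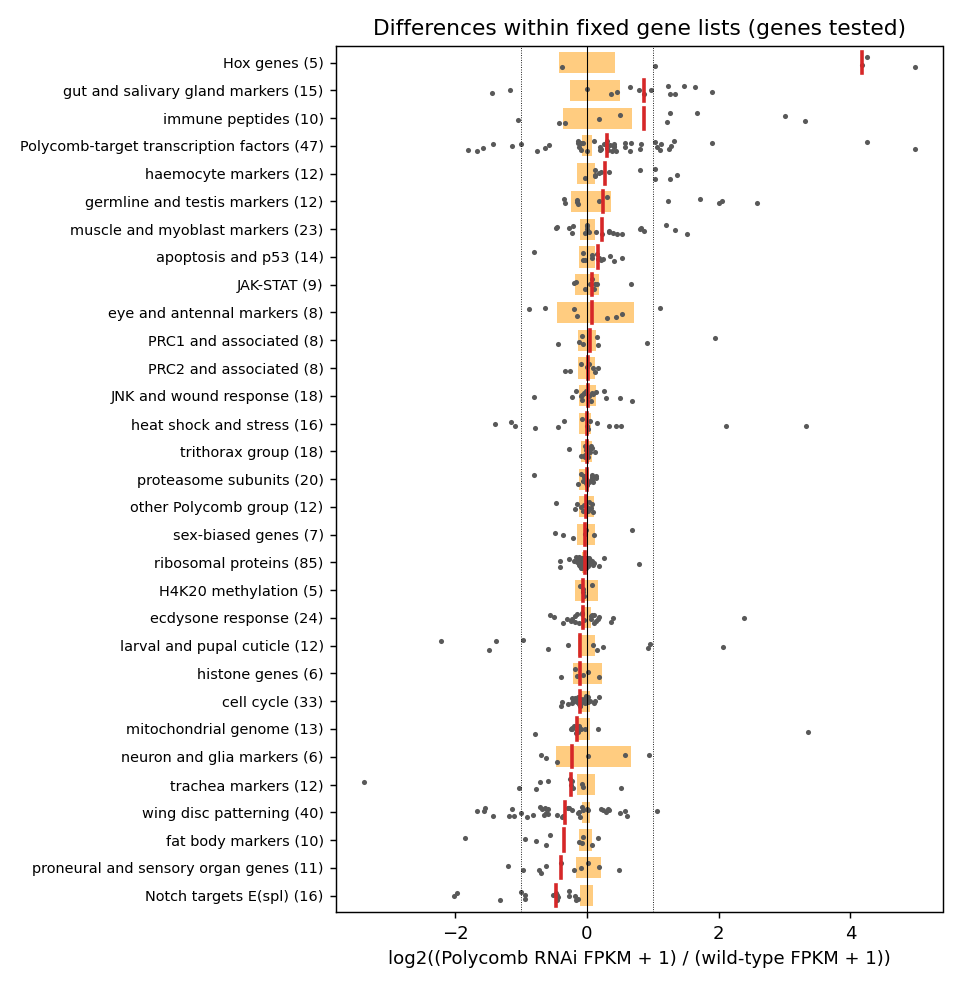
Log2 difference between Polycomb RNAi and wild type (x axis, pseudocount of 1) for tested genes of the fixed lists with a percentile, except the odorant and gustatory receptors. Grey points are genes (number tested in brackets), red lines are list medians, and orange bands are the central 95% of medians of matched random lists. The median of the Hox genes is 4.18 and that of the Notch targets -0.46; dotted lines mark a 2-fold difference.

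Among the genes for the Polycomb machinery, Su(z)2, a paralogue of the PRC1 subunit gene Psc, was at least 2-fold higher in Polycomb RNAi (6.37 FPKM in wild type and 27.4 FPKM in Polycomb RNAi). Psc was 13.2 and 25.8 FPKM, a log2 difference of 0.92. The other 6 tested genes of the PRC1 list lay within 2-fold, such as ph-d (12.2 and 8.76 FPKM), as did all 8 of the PRC2 list, all 12 other Polycomb group genes and all 18 trithorax group genes, the activating counterparts. In the list for H4K20 methylation, pr-set7, which encodes the methyltransferase, was 33.1 and 30.8 FPKM, and Hmt4-20, which encodes the enzyme adding further methyl groups, was 41.8 and 44.3 FPKM. All 5 of that list lay within 2-fold, and the medians of these 5 lists lay within the central 95% of random lists.

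Growth and survival genes differed by less than 2-fold with the pseudocount of 1. None of the 33 tested cell cycle genes was 2-fold apart, although their median of -0.11 lay at percentile 0.21. Matched random lists held on average only 0.37 higher and 0.44 lower genes. The kinase gene ial (Aurora B) was 72.5 and 55.1 FPKM in wild type and Polycomb RNAi and the Myc gene dm 44.8 and 34.3 FPKM. None of 14 apoptosis genes was 2-fold apart, with a median of 0.17 at percentile 99.6. It was 0.07, still at percentile 99.7, with both libraries scaled to the same sum. Without an expression minimum it was 0.12 at percentile 97.3, inside the random range. Random lists matched to these held on average 0.43 higher and 0.36 lower genes. The cell death gene rpr was 16.0 and 20.6 FPKM, and the largest difference in the list was that of wgn, at 25.4 and 14.2 FPKM. None of 9 tested JAK-STAT genes was 2-fold apart with the pseudocount of 1, though et (0.663 and 1.66 FPKM) was so in FPKM, with os, which encodes the ligand Unpaired, at 5.36 and 4.54 FPKM, and upd2 and upd3 below 1 FPKM in both libraries. None of 18 genes of the JNK and wound response was 2-fold apart with the pseudocount of 1, though Ets21C (0.35 and 1.16 FPKM) was so in FPKM, with puc at 13.7 and 16.9 FPKM. The medians of these last 2 lists lay within the random range.

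Developmental timing genes were close between the libraries. Of 24 tested ecdysone response genes, only Edg91, a cuticle gene, was at least 2-fold higher (2.86 and 19.1 FPKM in wild type and Polycomb RNAi), and the list's median of -0.06 lay at percentile 12.6. Blimp-1 was 31.2 and 20.9 FPKM and Hr46 34.2 and 23.9 FPKM. Cuticle genes went both ways, with 1 of 12 at least 2-fold higher (Pcp, 8.89 and 40.4 FPKM) and 3 at least 2-fold lower, namely Lcp9 (57.1 and 11.5 FPKM), Lcp65Ac (2.29 and 0.181 FPKM) and Cpr97Eb (1.78 and 0.0642 FPKM). Their median was -0.10, at percentile 7.98, but 0.12, at percentile 98.9 and thus above the random range, with a minimum of 5 FPKM. The share of cuticle genes at least 2-fold lower lay at percentile 99.8, against a random mean of 0.37 genes.

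Stress and immune genes differed without a common direction for heat shock. The small heat shock gene Hsp23 was 3158 FPKM in wild type and 1202 FPKM in Polycomb RNAi, and Hsp67Ba was 160.5 and 72.0 FPKM. Hsp70Bb was 0.961 and 18.6 FPKM, a value made uncertain by the near-identical Hsp70 copies. TotA, a secreted stress factor, was 42.3 and 185.9 FPKM. In all, 2 of 16 genes were at least 2-fold higher and 3 lower. Of 10 tested immune peptide genes, 5 were at least 2-fold higher, namely IM1 (listed at 0 in wild type and 8.96 FPKM in Polycomb RNAi), IM2 (0 and 7.0 FPKM), IM4 (0 and 2.18 FPKM), IM23 (0 and 1.4 FPKM) and the antifungal gene Drs (19.8 and 47.5 FPKM). Mtk was at least 2-fold lower (1.07 and 0 FPKM). The list's median was 0.86, at percentile 99.3, but it was 0.25, at percentile 97.1, with a pseudocount of 5 and 0.18 without an expression minimum. Only 5 of the 10 tested genes reached 1 FPKM in wild type. Markers of haemocytes, which take part in immune responses, were higher in the same library (median 0.27), and those of the fat body, the main source of immune peptides, were lower (median -0.34).

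Markers of other larval cell types differed between the libraries in different directions. Fat body markers had a median of -0.34, below that of all 10000 random lists, and of -0.12 without an expression minimum. Only 1 of 10 was at least 2-fold lower, the storage protein gene Lsp1gamma (1675 FPKM in wild type and 465.4 FPKM in Polycomb RNAi). Lsp1beta was 1070 and 696.1 FPKM and Fbp1 762.4 and 801.1 FPKM. Haemocyte markers were higher (median 0.27, percentile 99.96), with 4 of 12 at least 2-fold higher, namely He (8.72 and 24.2 FPKM), Pxn (5.26 and 14.1 FPKM), eater (3.72 and 8.66 FPKM) and Hml (2.76 and 6.68 FPKM). With both libraries scaled to the same sum, eater and Hml lay within 2-fold (log2 differences of 0.95 and 0.96). The median was then 0.17, still at percentile 99.9. Muscle and myoblast markers had a median of 0.23 (percentile 99.9), or 0.13 (percentile 99.95) with both libraries scaled to the same sum. Of these 23, the muscle genes TpnC73F (8.19 and 25.3 FPKM), wupA (8.28 and 22.5 FPKM) and Prm (1.79 and 5.41 FPKM) were at least 2-fold higher, while the myoblast genes twi (11.1 and 11.2 FPKM) and Mef2 (22.9 and 23.5 FPKM) were nearly equal. Tracheal markers had a median of -0.24 at percentile 0.13, with 10 of 12 within 2-fold. The 2 at least 2-fold lower were obst-A (220.0 and 20.2 FPKM) and trh (20.7 and 9.65 FPKM). All tested markers of haemocytes (12), muscle (23), trachea (12) and fat body (10) reached 1 FPKM in wild type as well.

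Of 15 tested gut and salivary gland markers, 6 were at least 2-fold higher and 2 lower, with a median of 0.87 at percentile 99.8. The median was 0.41 without an expression minimum, 0.28 with a pseudocount of 5 and 1.36 with a minimum of 5 FPKM. The salivary glue genes Sgs7 (29.6 and 94.0 FPKM in wild type and Polycomb RNAi), Sgs8 (6.88 and 21.0 FPKM) and Sgs5 (3.53 and 15.8 FPKM) were higher, and the gut protease gene epsilonTry (2.5 and 0.293 FPKM) was lower. Of the tested markers, 9 of 15 for gut and salivary gland and 8 of 12 for germline and testis reached 1 FPKM in wild type. Of 12 tested germline and testis markers, 5 were at least 2-fold higher, all of them genes of the male germline, namely Mst84Dc (0.601 and 8.61 FPKM), Mst84Db (0 and 3.14 FPKM), Mst84Da (0 and 3.02 FPKM), Mst87F (1.20 and 6.24 FPKM) and dj (0 and 1.35 FPKM). The early germline genes vas (0.18 and 0.18 FPKM) and bam (0.30 and 0.69 FPKM) stayed below 1 FPKM. The list's median of 0.24 was within the random range (percentile 91.7), but 0.22, at percentile 98.6, with a pseudocount of 5. Its share of 2-fold higher genes lay at percentile 99.65, against a random mean of 1.47 genes. Of these genes, Mst84Da, Mst84Db, Mst84Dc and dj passed the minimum through the RNAi library only. None of 6 tested neuron and glia markers was 2-fold apart with the pseudocount of 1, but n-syb (1.09 and 0.289 FPKM), Rbp9 (0.352 and 1.01 FPKM) and moody (2.71 and 6.13 FPKM) were so in FPKM and with a pseudocount of 0.1. Of 8 eye and antennal markers, oc alone was at least 2-fold higher, and ss was 6.91 and 3.32 FPKM, at least 2-fold lower only in FPKM and with a pseudocount of 0.1. None of 7 sex-biased genes was 2-fold apart, with roX1 at 138.1 and 107.7 FPKM and roX2 at 70.2 and 49.9 FPKM. The eye colour gene w, a common marker on transgenes, was 61.5 and 27.0 FPKM, while Act5C was 4541 and 4714 FPKM. Of the 3 tested genes in a list of adult tissue genes, Obp99a (35.8 and 7.30 FPKM) and Obp44a (74.9 and 19.1 FPKM) were at least 2-fold lower.

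Housekeeping groups lay close together. None of the 85 tested ribosomal protein genes and none of the 20 tested proteasome genes was 2-fold apart with the pseudocount of 1, with medians of -0.03 and 0.0042. In FPKM the variants RpL22-like (0.413 and 1.44 FPKM) and Rpt3R (4.17 and 1.98 FPKM) were so. None of 6 histone genes was 2-fold apart (median -0.10). Transcripts of the mitochondrial genome had a median of -0.14 at percentile 1.30, with mt:CoIII at 10359 and 8824 FPKM in wild type and Polycomb RNAi. Only mt:ND4L, listed at 0 in wild type and 9.19 FPKM in Polycomb RNAi, was at least 2-fold higher. Of 5 tested odorant and gustatory receptor genes, none was 2-fold apart with the pseudocount of 1, though Gr61a (1.72 and 0.853 FPKM) was so in FPKM. Of the 32 lists with a percentile, 7 lay above the random range and 7 below it.

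By the fixed rule, the 10 largest positive differences were all small RNAs listed at 0 in wild type, from snoRNA:Psi28S-2949 (52.4 FPKM in Polycomb RNAi) to snoRNA:nop5-x16-a (4737 FPKM). The others were mir-4941 (599.1 FPKM), snoRNA:Psi28S-1837a (119.6 FPKM), snoRNA:Psi28S-3316a (117.7 FPKM), mir-4962 (83.5 FPKM), snoRNA:Psi28S-1175b (77.4 FPKM), mir-998 (70.7 FPKM), snoRNA:Psi18S-1854a (67.7 FPKM) and snoRNA:Psi28S-2622 (67.3 FPKM). Of the 10 largest negative differences, 9 were non-coding entries listed at 0 in Polycomb RNAi, led by CR40502 (1723 FPKM in wild type) and CR41590 (1646 FPKM). The tenth was RIC-3, a gene for a chaperone of acetylcholine receptors, at 101.7 FPKM in wild type and 1.03 FPKM in Polycomb RNAi. Among small RNA names reaching 1 FPKM, 27 were listed at 0 in wild type alone and 20 in Polycomb RNAi alone. Of 136 small RNA names tested, 45 were at least 2-fold higher and 37 at least 2-fold lower.

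Among protein-coding genes with a single table name, a ranking added after the values were seen, the largest positive differences were CG11697 (0.351 FPKM in wild type and 44.9 FPKM in Polycomb RNAi), Abd-B, Ubx, CG42680 (0 and 17.6 FPKM), PGRP-SB2, a peptidoglycan recognition gene (0.392 and 24.6 FPKM), Scr and IM3 (0 and 13.3 FPKM). The forkhead gene fd96Cb was 0.444 and 13.2 FPKM and the receptor tyrosine kinase gene Ret 2.52 and 18.4 FPKM. The largest negative differences after RIC-3 were the cuticle protein gene Cpr64Ac (32.8 and 0.273 FPKM), CG34247 (27.2 and 0.979 FPKM), CG2663 (15.2 and 0.235 FPKM), the xanthine dehydrogenase gene ry (21.3 and 0.831 FPKM), CG7465 (22.1 and 0.899 FPKM), obst-A and l(3)87Df (216.7 and 20.7 FPKM).

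H4K20me1 in wild-type discs was enriched in 7885 peaks that together covered 23.7 Mb. Peaks were broad, with a median width of 2200 bp, quartiles of 1400 and 3600 bp and a range from 200 to 57000 bp. The 5 main arms held 7836 peaks. Arm 3R had 1956 peaks (24.8%, 95% interval 23.9 to 25.8), 3L had 1614 (20.5%, 19.6 to 21.4), 2R had 1591 (20.2%, 19.3 to 21.1), X had 1367 (17.3%, 16.5 to 18.2) and 2L had 1308 (16.6%, 15.8 to 17.4). Relative to the span from the first to the last peak, density was highest on 2R at 78.6 peaks per Mb, was 70.0 on 3L and 70.1 on 3R, and was lower on X at 61.1 and on 2L at 57.1. The small chromosome 4 carried 28 peaks, 23.0 per Mb, which covered 3.78% of its span against 25.0% on 2R. A further 21 peaks lay on unplaced or heterochromatic sequence.

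The highest-scoring peak in the authors' list was also the widest, on chromosome X from 1465001 to 1522000 (dm3, 57000 bp). It was followed by peaks on 3L from 17946601 to 17993400 (46800 bp, score 7669), on 3R from 27723001 to 27759400 (36400 bp, score 5600), on 2L from 640401 to 687000 (46600 bp, score 4943) and on 3R from 27677601 to 27713600 (36000 bp, score 4820). The score tracked the width across peaks (Spearman rho 0.724; peaks are not replicates). Because the scale of the score is not given, this may come from how the score was computed. Peaks of at least 10 kb numbered 196 (2.49% of peaks) and held 12.3% of the covered sequence. Mappable sequence and input coverage were not taken into account. The genes under these peaks were not analysed here, and no relation between H4K20me1 and the expression differences is given.

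**Figure D3:**
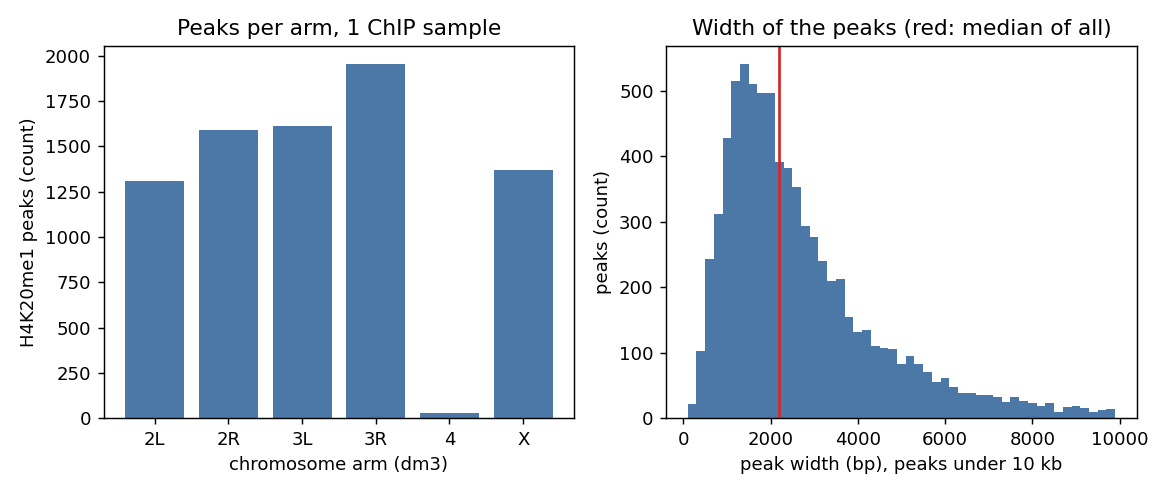
Number of H4K20me1 peaks per chromosome arm (left, count, dm3, 1 ChIP sample) and the distribution of peak widths in bp for peaks under 10 kb (right, count), with the median of all peaks, 2200 bp, as a red line. Arm 3R holds most peaks (1956) and chromosome 4 only 28; 196 peaks of at least 10 kb are not drawn.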

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

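The treatments of duplicate names and small RNAs were added after seeing the data; the other settings were fixed beforehand. The counts of 388 higher and 282 lower genes depended on thresholds. With a pseudocount of 5 they were 134 and 107, with a minimum of 5 FPKM 189 and 186, with a 1.5-fold threshold 719 and 569, and with a 4-fold threshold 105 and 66. A pseudocount of 0.1 gave 570 and 415. Dropping the expression minimum changes neither count by construction. Scaling each column to the same sum moved the median of all tested genes from -0.0032 to -0.10 and gave 370 higher and 325 lower. The summed FPKM was 916814 in wild type and 985157 in Polycomb RNAi, and CG41421 alone was 86281 and 161123 FPKM. The shift from this scaling thus depends on that 1 entry. Median centring gave 389 and 279. Summing names of the same gene gave 379 and 269, and leaving out small RNAs 343 and 245. The number of lists outside the random range was 14 and ran from 12 to 15 over the alternatives. The Hox, Polycomb target, wing patterning and Notch target lists kept their side of the random range under every alternative that gave a value, though the Hox median went from 4.18 to 0.74 without a minimum; with a minimum of 5 FPKM only 4 Hox genes were left, too few for a percentile. Lists that changed side were the proneural list (-0.08) and the cuticle list (0.12, from -0.10) with a minimum of 5 FPKM, the immune (0.25) and germline (0.22) lists with a pseudocount of 5, and the apoptosis (0.12), neuron (-0.11) and proteasome (0.06) lists without a minimum. The share of peaks on X was 17.3% in the upper-scoring part of the list as well. The 155 genes named by the fixed rule were also checked, but not those named outside it, such as rho, kn, mid, disco, lbl and ap. Among the 155, no call changed direction under another pseudocount or scaling, but calls were lost. A pseudocount of 5 put 18 within 2-fold, among them abd-A (0.44), cad (0.66), sens (-0.52), HLHm5 (-0.42), Pxn (0.89), eater (0.65), Hml (0.59), Prm (0.62), trh (-0.81), oc (0.32), IM4 (0.52) and IM23 (0.36). Scaling to the same sum put 3 within 2-fold, abd-A (0.99), eater (0.95) and Hml (0.96), and median centring 1, HLHm5. A pseudocount of 0.1 put 13 more beyond 2-fold, among them ac (-1.01), and scaling to the same sum 2, ac (-1.07) and Tsf1 (-1.03). Overlaps of peaks with genes, and the other settings intended for them, were not run. No paired analysis was possible because each genotype has 1 library, and no library could be left out. Depth limits the low genes most: the files hold no counts, so a value of 0 cannot be given an upper limit.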

Other observations

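The Hox list and its percentile were fixed before the data were examined; the tests of neighbouring genes, small RNAs and shared names, and the use of the Hox genes to weigh the Pc level, were chosen after the results were seen. Several genes outside the fixed lists stood apart. A pair of abundant neighbouring genes was higher in Polycomb RNAi, Nplp4, a neuropeptide-like precursor gene (219.0 FPKM in wild type and 1110 FPKM in Polycomb RNAi), and CG15353 (1510 and 4391 FPKM). The forkhead genes fd96Ca (0.175 and 4.72 FPKM) and fd96Cb (0.444 and 13.2 FPKM) were higher together. The BMP-binding gene cv-2, required for the crossveins of the wing, was lower (14.6 and 4.17 FPKM), as were CG16885 (58.4 and 10.9 FPKM) and CG16884 (60.0 and 8.96 FPKM), known in the reference as Vajk2 and Vajk3. The adjacent genes l(3)87Df and ry were both lower, at 216.7 and 20.7 FPKM and at 21.3 and 0.831 FPKM. A difference in genetic background between the driver line with its balancer and the cross was not tested for any of these.

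Genes that differed lay side by side more often than chance placement gives. Neighbours here are consecutive tested genes, so untested genes can lie between them. Among 8195 tested protein-coding genes in chromosomal order, 81 neighbouring pairs differed at least 2-fold in the same direction. In 10000 shuffles within chromosomes the mean was 16.9 and the maximum 33. Among genes reaching 5 FPKM the number was 33, against a mean of 4.97 and a maximum of 15. Pairs in opposite directions numbered 26 against a mean of 15.5. There were 15 runs of 3 or more genes. They included the 7 genes from IM23 to CG15068, and modSP with Ubx, abd-A and Abd-B. Others were the 3 Doc genes, the glue genes Sgs3, Sgs7 and Sgs8, and the Mst84D genes with CG31496. One hypothesis is that blocks of chromatin change together, but some of these runs hold related genes, such as the Doc, glue and Mst84D genes. Shared tissue specificity, reads shared between copies or between overlapping genes, or a different tissue content may give the same 81 pairs. These were not separated, and the runs were not sorted by gene family.

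Pc RNA was nearly equal in the 2 libraries, at 14.6 FPKM in wild type and 13.0 FPKM in Polycomb RNAi. In otherwise equal tissue, the Hox genes would argue against an RNAi library without loss of Polycomb function and against an exchange of the labels. Their median and their share of 2-fold higher genes both lay at percentile 100 of matched random lists. Both percentiles rest on the same 5 tested genes. Equal tissue is not shown, since the medians were -0.34 for fat body, 0.27 for haemocyte and 0.87 for gut and salivary gland markers. The last list mixes organs, with salivary glue genes such as Sgs7 higher and the gut protease genes epsilonTry and betaTry lower. Its median was 0.41 without an expression minimum. Without equal tissue, neither explanation is excluded. Reads of the hairpin transgene counted as Pc may hide a loss of Pc RNA; this cannot be told apart here, since the file gives only a value per gene (12.96 FPKM in the RNAi library) and none along it. Tissue of other segments carried along in the dissection also stays open for the Hox genes: 4 of them, from Scr to Abd-B, were higher, and a mixture of tissues could bring this.

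Small RNAs were often present in 1 library only. Of 132 small RNA names reaching 5 FPKM, 44 (33.3%) were listed at 0 in the other library, against 16 (0.222%) of 7219 other names. Chance detection of short RNAs in FPKM data is a candidate explanation. Of the 47 small RNA names present in 1 library alone and reaching 1 FPKM, 57.4% were absent from wild type. The exact 95% interval from 42.2% to 71.7% holds an even split. Any cause without a common direction would give an even split too, so the split does not single out chance detection. A rise of small RNAs as a class cannot be told apart from chance detection, because the interval is wide.

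Some differences were between names of the same gene. Of 29 names at least 2-fold apart that share a reference gene with another name, 22 lay within 2-fold once the names were summed, but a large value of the other name brings the sum within 2-fold by itself. Of the 7 genes whose sum would have stayed 2-fold apart had the other name not differed, 4 lay within 2-fold when summed (57.1%, exact 95% interval 18.4% to 90.1%), so reads of a gene divided between its names by the authors' quantification cannot be told apart from other causes for the class, since the genes are too few. The name wash was 0.0095 and 14.0 FPKM in wild type and Polycomb RNAi while CG13176, the same gene, was 12.4 and 0.0454 FPKM, and the sums were 12.4 and 14.0 FPKM. By contrast, E(spl)m4-BFM and m4, also the same gene, were both lower, with sums of 65.1 and 13.5 FPKM. No biological explanation was tested for these names.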
